A study of Mus musculus with 2 samples.

How the data were processed

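The study measured where Cdx2, a caudal-type homeobox transcription factor, sat on the genome of mouse embryonic stem (ES) cells. The cells carried a transgene for Cdx2 with a FLAG tag at its C-terminus in the ROSA26 locus, under a Tet-Off promoter that doxycycline keeps silent. There was 1 Cdx2-FLAG library, made by chromatin immunoprecipitation with an anti-FLAG gel, and 1 control library. Each was made from chromatin of 100000000 cells, per the labels' protocols, and the cells of the Cdx2-FLAG library were at passage 30. Control cells carried an empty vector or the repressed transgene, and were kept in 0.2 ug/ml doxycycline, the transgenic ones for 48 to 60 hours. The control library was sequenced in lanes 7 and 8 of a flow cell, by the read names, and the labels do not say which control cells filled which lane.

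The authors placed the reads with ELAND on mm9, per the submitters' processing notes and the layout of the deposited alignments. The reads were 36 bases long, with up to 2 mismatches allowed. A comparison of 20000 reads per library with the genome sequence showed that the listed mismatch numbers referred to the first 32 bases, for 99.9% of the sampled reads in each library. The deposited alignments hold 1 line per read with its number of places at 0, 1 and 2 mismatches, and no normalisation was applied. The peak list comes from the authors, who compared tags in each peak with control tags in the same region, corrected for total tags. It gives for each peak a count of tags as the authors determined it, a centre and nearby genes. The peak caller and its threshold are not given in the sources used here. The list gives no start or end of a peak, so a window of 500 bp round the listed centre replaced the region that had been planned. A deposited file of placed reads holds 5719341 lines for 5170015 read names, and its lines within 1000 bp of a centre equalled the authors' tag count for 53.5% of the peaks.

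A read counted as uniquely placed when it had exactly 1 place at its lowest number of mismatches, and it was assigned to the midpoint of its 32 matched bases. Reads on chromosomes 1 to 19, X and Y were used, 5215228 for Cdx2-FLAG and 12634906 for the control. For each peak the ratio of Cdx2-FLAG to control reads was corrected for these totals and given with its exact conditional (Clopper-Pearson) 95% interval. A peak counted as enriched when the lower bound was above 2. Against 0 control reads a fold was computed from a floor of 3 control counts and written as at least that fold. It leaves out counting error of the Cdx2-FLAG reads, so the exact 95% lower bound, which is lower, stands beside it. Shares have Wilson 95% intervals. With 1 library per group no test across conditions was possible, so ratios compare these libraries and not the conditions. Reads had no molecular identifiers, so intervals and floors cover counting error only.

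Genes were the protein-coding genes of GENCODE vM1 on mm9, 22225 symbols with 1 entry each. Distances ran to the nearest annotated transcription start. Peak location was set beside 10000 random positions and 10000 control reads. A gene had a peak when a centre lay within 20 kb of a start. For 10 gene lists fixed beforehand (trophectoderm, pluripotency, intestine, posterior axis and Wnt, Hox, liver, muscle, neural, housekeeping and olfactory receptors) the number of members with a peak was compared with 10000 random lists matched on gene length in 20 bins. The empirical p was two-sided, with Benjamini-Hochberg adjustment over the 10 lists. The smallest p that these lists can give is 0.0002. The p of a list against runs of neighbouring genes took the place of its own p in the same adjustment. Genes are not replicates, so these values describe the list and not the experiment. Sox1 was not found in the annotation, and Tcfcp2l1 and Tfcp2l1 in the pluripotency list were 1 gene. Fixed motifs, among them CDX (YMATAAA), were searched on both strands within 100 bp of each centre and in flanks of the same length 1000 bp away on either side. The strand lag was the distance with the most pairs of plus and minus strand read starts in 5 bp bins, averaged over 5 neighbouring bins, from 50 bp upwards; this minimum leaves out a larger maximum at 30 bp. Windows of 500 bp with at least 10 Cdx2-FLAG reads and a lower bound above 2 were called without the peak list.

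Named peaks were the 20 with the highest lower bound of the ratio after collapsing reads with the same start and strand. Named genes were, in each list, up to 4 members whose best peak within 20 kb had the highest such bound. Cdx2, Pou5f1, Nanog, Sox2, Eomes, Hoxa7, Hoxb9 and Cdx1 were named whatever their values. This rule, the gene lists, the motifs, the tests and a set of alternatives were fixed before the data were examined. Alternatives fixed then were collapsed reads, exact matches, scaling by reads outside peaks, reads with up to 10 places, a lower bound above 5, peaks with at least the median tag count, peaks merged within 500 bp, distances of 5 and 100 kb, random lists without length matching, the motif core, motif shares of reads, 50% overlap, a minimum of 20 reads per window and each distinct sequence counted once. Windows of 200 and 1000 bp, each control lane alone, peaks with at least 15 tags, division by the ratio outside peaks at the same GC content, GC-matched lists, runs of neighbouring genes for Hox and the exclusion of copies of a repeated sequence were added after seeing the data. Copies of that sequence were all places in mm9 with at most 12 mismatches to a 47 bp consensus, and a peak lay at a copy when its centre was within 150 bp. Neither the genome sequence nor the annotation used here marks repeats, so no repeat family is named.

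All steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, numba 0.67.0 and matplotlib 3.10.9, and the genome was indexed with samtools 1.23.1. The functions were tested on simulated data. Of 20000 simulated sites with a true ratio of 1, 0.015% had a lower bound above 2, against 61.9% at a true ratio of 10 and a control mean of 2.5 reads. These rates hold for sites that were not chosen on the reads, and not for the listed peaks. Among 400 random lists 2.25% had a p below 0.05. Of 200 simulated bound windows 99.5% were called, with 0 others. These windows were set far above a flat background. The listed peaks had a median of 6 Cdx2-FLAG reads, below the minimum of 10 per window, so these rates do not describe them.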

Results

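The data were 1 Cdx2-FLAG ChIP-seq library and 1 control library from mouse ES cells, with no replicates. The Cdx2-FLAG library held 17588028 reads, of which 5287201 (30.1%) had a unique place in mm9. The control held 22835793 reads, of which 12744459 (55.8%) had a unique place. The authors' list held 59098 peaks with at least 6 tags each and a median of 8.

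The first comparison asked how far reads of the Cdx2-FLAG library gathered at the listed sites relative to the control. The Hoxa cluster on chromosome 6 held some of the clearest sites. The peak inside Hoxa7, a gene of trunk patterning, had 64 Cdx2-FLAG reads and 2 control reads, a ratio of 77.5 (95% interval 20.6 to 654, lower bound 11.7 with collapsed reads). Zfp42, a marker of undifferentiated ES cells, had a peak 16594 bp downstream of its start with 47 reads against 2, a ratio of 56.9 (14.9 to 484). Krt20, a keratin of the intestinal lining, had an intronic peak with a ratio of 39.97 (10.2 to 344), and a peak upstream of Wnt5a had a ratio of 27.9 (10.2 to 107). Over all listed peaks, 8.23% (8.21 to 8.25) of the Cdx2-FLAG reads and 1.204% (1.198 to 1.21) of the control reads lay within the 500 bp windows. The ratio of these shares was 6.83 (6.79 to 6.87), and it was 4.28 in windows of 1000 bp. The lower bound of the ratio was above 2 for 16628 peaks (28.1%) and above 1 for 36773. With control lane 7 or lane 8 alone the first count was 7432 or 7588. The pooled ratio was 5.16 (5.09 to 5.23) for peaks with 6 tags and 31.4 (29.9 to 33.0) for peaks with 30 to 59 tags. It was 27.2 (24.2 to 30.6) for the 47 peaks with 60 or more tags, and 24.3 and 15.1 in the last 2 classes with collapsed reads. Peaks with 6 or 7 tags made up 45.8% of the list, and their median numbers of Cdx2-FLAG reads were 5 and 6. The authors chose the peaks, and counted their tags, from this library and compared them with the control, so an excess at the peaks and its rise with tags were built in. The intervals do not cover that choice, and the counts of peaks above a bound are no error-controlled calls.

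**Figure D1:**
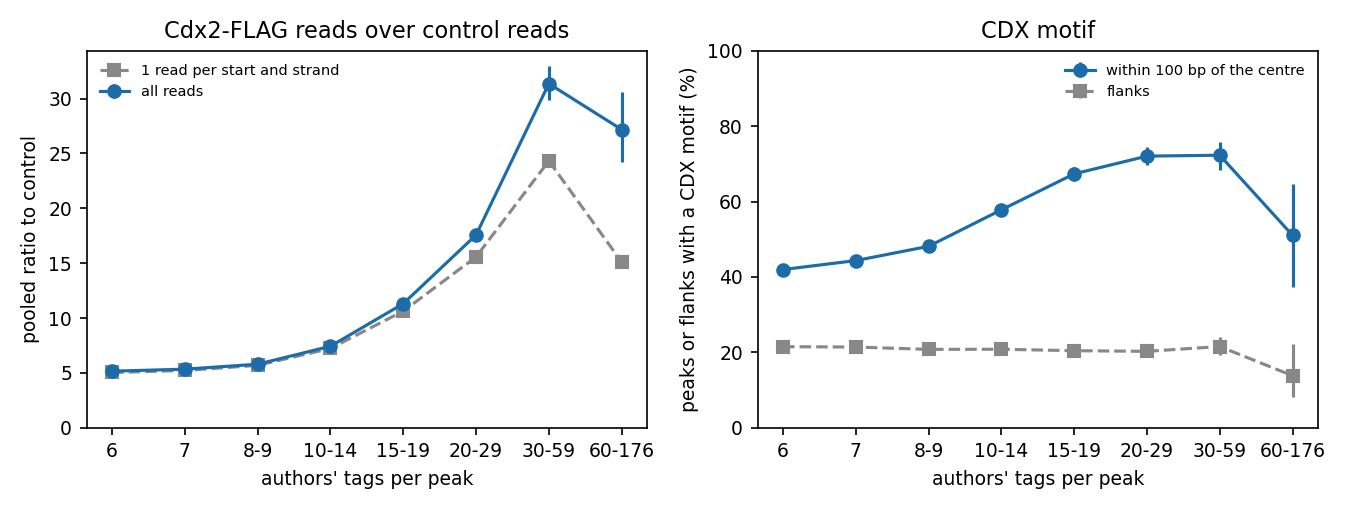
Pooled ratio of Cdx2-FLAG to control reads (left) and percent of peaks or flanks with a CDX motif (right) by the authors' tag count per peak, with 95% counting intervals on all reads and on the motif shares. The ratio was 5.16 at 6 tags and 31.4 at 30 to 59 tags, and the motif share was 41.98% and 72.3% in the same classes. At 60 or more tags they were 27.2 and 51.1%.

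The 20 peaks with the highest bounds from collapsed reads lay mostly far from gene starts, with 9 in introns and 11 between genes, and 6 within 20 kb of a start. They had 28 to 66 tags and 54 to 106 Cdx2-FLAG reads, and 18 of them had 0 control reads. A peak in an intron of Dlgap1, which encodes a scaffold protein of synapses, had 106 reads from 49 distinct starts against 0, at least 85.6-fold against the floor of 3 control reads (exact lower bound 68.4, and 28.95 with collapsed reads). The intronic peak of Slc25a17, a peroxisomal carrier, was at least 80.8-fold higher (exact bound 64.5), and that of Trim24, a transcriptional cofactor, at least 69.5-fold (55.3). The peak with the highest bound from collapsed reads, 41.2, lay between genes on chromosome 2, 252868 bp from Tmco5. With all reads it was at least 79.1-fold higher (63.2). Other peaks of this group lay in introns of Csmd3, Kcnu1, Spag16 and Magi2, or between genes with Cntnap5a, Gm7263, Vmn1r26, Ralyl, Gm6657, Fsip2, Gm6557, Scarb2, Prss47 or Lnpep as the nearest gene. These 14 ran from at least 43.6-fold (34.3) at Prss47 to at least 73.5-fold (58.6) at Kcnu1 and Cntnap5a. Collapsed reads gave lower bounds of 27.1 at Prss47, 30.8 at Kcnu1, 37.5 at Cntnap5a, 35.7 at Trim24 and 40.6 at Slc25a17. The intronic peaks of Acnat1 and Lgi1 each had 83 reads against 1 control read, a ratio of 201 (35.1 to 8037). All 20 had a CDX motif within 100 bp, for example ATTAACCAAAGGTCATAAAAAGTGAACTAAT at positions 81186777 to 81186807 of chromosome 15 in the Slc25a17 intron. Of the 20 peaks, 19 lay on copies of 1 repeated sequence of 47 bp, and the peak near Tmco5 did not. The highest tag counts of the list were not always matched by unique reads. The peak with 151 tags, nearest to Actl7b and chosen after its values were seen, had 4 Cdx2-FLAG reads with a unique place in its window.

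The gene lists asked which groups of genes had binding sites within 20 kb of a start, beside 12751 (57.4%) of all 22225 genes. Hox genes, which set position along the body axis, had a peak near 33 of 39 members against a median of 19 (13 to 25) in random lists. The permutation p adjusted over 10 lists was 0.0009999, from the smallest p that 10000 lists can give. The Hoxa cluster held 16 peaks, or 110 per Mb with 20 kb on either side, with up to 39 tags. Hoxc held 11 peaks, Hoxb 8 and Hoxd 5. The peak in Hoxa7 was also the best peak of Hoxa3, Hoxa5, Hoxa6, Hoxa9 and Hoxa10, whose starts lay within 20 kb. A peak beside Hoxa4 and Hoxa5, at position 52151071 and chosen after its values were seen, had 36 tags and a ratio of 35.5 (11.4 to 179). Hoxb9 had 5 peaks within 20 kb, the best with 10 reads against 1 and a ratio of 24.2 (3.45 to 1051). Hoxb13, Hoxc13, Hoxd1, Hoxd10, Hoxd11 and Hoxd12 were the 6 members without a peak. Among peaks with at least 15 tags, 17 Hox genes had one against a random median of 2. Neighbouring Hox genes shared peaks, and against runs with the same numbers of neighbouring genes the 33 genes compared with a median of 22 (13 to 31). These runs were not matched on their span in bp, so sharing of peaks among closely packed genes may remain in the comparison. The permutation p was 0.0150 unadjusted and 0.0750 adjusted over the 10 lists, which did not pass. With at least 15 tags, the 17 Hox genes compared with a median of 3 (0 to 9) in such runs (adjusted permutation p = 0.0020). These genes shared few peaks. With 20 kb on either side, Hoxa held 3 peaks with at least 15 tags, Hoxc 3, Hoxd 1 and Hoxb 0. Within 100 kb all 39 had a peak against a random median of 37 (adjusted permutation p = 0.698).

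**Figure D2:**
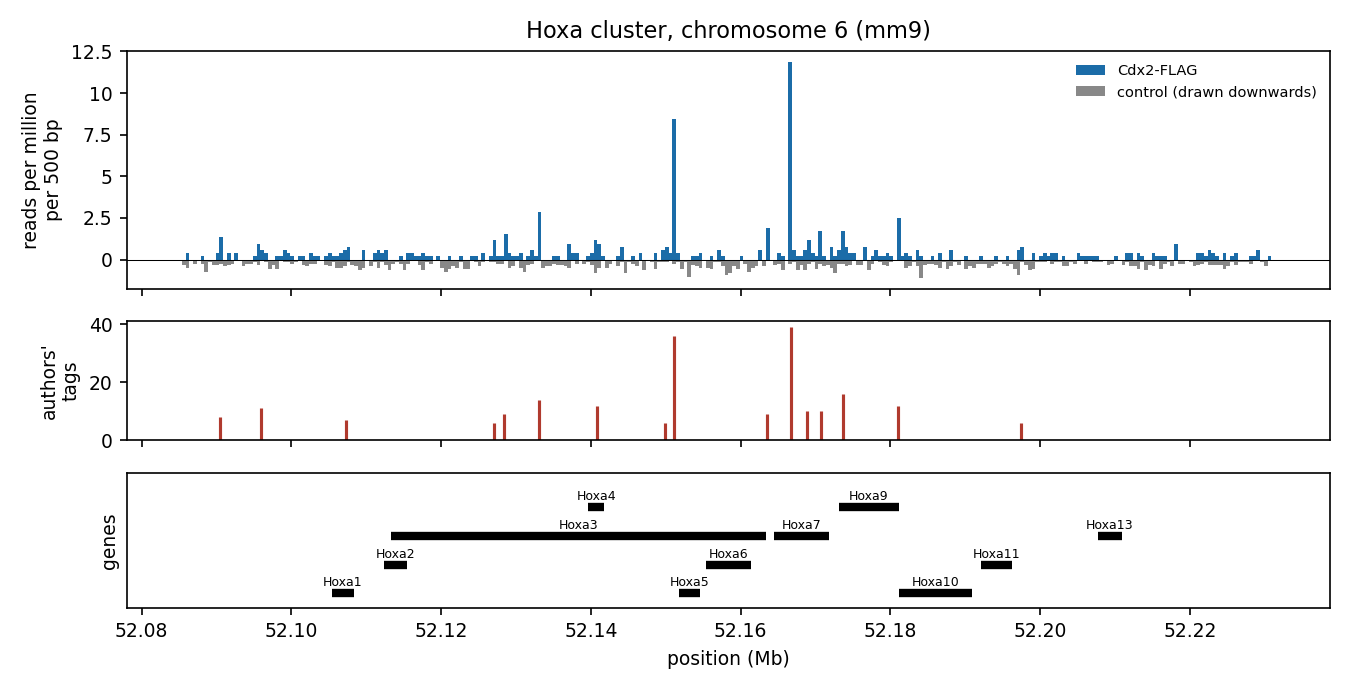
Hoxa cluster on chromosome 6 of mm9. Top, uniquely placed reads in 500 bp bins, scaled to library size, for Cdx2-FLAG (upwards) and control (downwards); middle, tags of each listed peak; bottom, Hox genes. The highest bin lies at the peak inside Hoxa7 (39 tags) and the next at the peak beside Hoxa5 (36 tags).

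Pluripotency genes had a peak near 20 of 27 members against a random median of 14 (adjusted permutation p = 0.0800), which did not pass the correction. Klf5, a zinc finger factor of ES cells and trophectoderm, had 4 peaks, the best 17603 bp upstream with 28 reads against 1 and a ratio of 67.8 (11.2 to 2774). Lefty1, an inhibitor of Nodal signalling, had a best ratio of 29.1 (4.30 to 1243). Nr0b1 on chromosome X had 8 reads against 0, at least 6.46-fold more than the control (exact bound 4.14). Trophectoderm genes had a peak near 19 of 28 members (random median 15, adjusted permutation p = 0.333). Tfap2a, a factor of the trophoblast lineage, had an intronic peak with 27 reads against 1 and a ratio of 65.4 (10.8 to 2678). Krt18, an epithelial keratin, had a best ratio of 11.3 (3.16 to 61.4), Ascl2 12.1 (2.58 to 114), and Msx2 had 7 reads against 0, at least 5.65-fold (exact bound 3.49). Intestine genes had a peak near 22 of 29 members (random median 17, adjusted permutation p = 0.246). Besides Krt20, Guca2a, which encodes the peptide guanylin, had a peak 17842 bp upstream with a ratio of 32.7 (8.22 to 284). Cdh17, an intestinal cadherin, had a ratio of 26.6 (3.87 to 1147) 1877 bp upstream of its start, and Fabp1, a fatty acid binding protein, had 10 reads against 0, at least 8.08-fold (exact bound 5.43).

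Posterior axis and Wnt genes had a peak near 18 of 29 members (random median 16, adjusted permutation p = 0.582). Besides Wnt5a, Rarb, a retinoic acid receptor, had a ratio of 24.2 (5.89 to 214), Wnt8a 13.3 (2.91 to 124), and Nkx1-2 had 6 reads against 0, at least 4.85-fold (exact bound 2.85). Muscle genes had a peak near 14 of 20 members (random median 11, adjusted permutation p = 0.543), among them Myod1 with a ratio of 36.3 (5.59 to 1530) and Tnnt3 with 10.5 (4.23 to 31.2). Myh1 had a ratio of 21.8 (3.02 to 956) and Ryr1 12.1 (2.58 to 114). Liver genes had a peak near 9 of 20 members (random median 10, adjusted permutation p = 0.721). Cps1 of the urea cycle and the fibrinogen genes Fga and Fgb, which share a peak, had 7 reads against 1 and a ratio of 16.96 (2.18 to 764), and Cyp7a1, an enzyme of bile acid synthesis, had 19.4 (2.60 to 860). Liver genes near a peak above 2 were 4, and 1 after division at the same GC content. Housekeeping genes went from 2 to 1, while posterior axis and Wnt genes stayed at 8, muscle genes at 5 and neural genes at 3. Neural genes had a peak near 9 of 19 members (random median 11, adjusted permutation p = 0.582), with Nes and Syn1 each at 7 reads against 0, at least 5.65-fold (exact bound 3.49), Map2 at a ratio of 12.1 (2.58 to 114) and Rbfox3 at 14.5 (1.76 to 669). Housekeeping genes had a peak near 11 of 20 members (random median 10, adjusted permutation p = 0.911). Psmb4 had 9 reads against 0, at least 7.27-fold (exact bound 4.78), and Sdha, Gapdh and Tbp had ratios of 11.3 (3.16 to 61.4), 5.33 (1.71 to 19.6) and 4.85 (1.30 to 21.99). Olfactory receptor genes had a peak near 701 of 1113 members (random median 646, adjusted permutation p = 0.0009999). Their median GC content over 40 kb was 38.2% against 44.4% for all genes, and against random lists matched on it the median was 711 (684 to 738). For peaks with at least the median tags, 430 of these genes were below a GC-matched median of 482 (453 to 510, unadjusted permutation p = 0.0004). For peaks with a bound above 2, 287 were below 328 (302 to 353, unadjusted permutation p = 0.0026). Random lists drew genes singly, and runs of neighbouring genes were not drawn for this list, where neighbours can share a peak. The p-values of the olfactory receptor list may thus be too small and its ranges too narrow. Olfr101 and Olfr102 shared a peak 9875 bp upstream of Olfr101 with 50 reads against 1, a ratio of 121 (20.8 to 4879). Olfr584 and Olfr585 shared a peak 4388 bp downstream of the start of Olfr584 with 38 reads against 0, at least 30.7-fold (exact bound 23.8). Both of these peaks lay at copies of the 47 bp sequence.

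**Figure D3:**
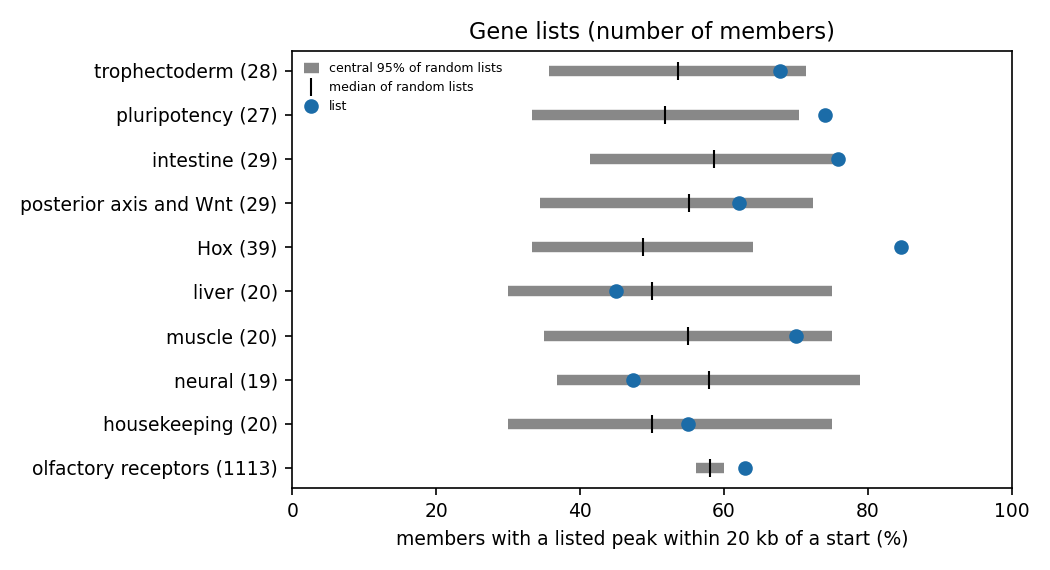
Percent of members of each gene list with a listed peak within 20 kb of a start (points) beside the median (ticks) and the central 95% (bars) of 10000 random lists matched on gene length. The Hox, olfactory receptor and pluripotency lists lay above their bars, with 33 of 39, 701 of 1113 and 20 of 27 members; the pluripotency list did not pass the adjustment over 10 lists.

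Another 6 genes were read whatever their values. Cdx2 itself had 1 peak within 20 kb, 12401 bp upstream, with 6 reads against 2 and a ratio of 7.27 (1.30 to 73.6). Pou5f1, which encodes Oct4, had 8 reads against 4 at a peak 17497 bp upstream, a ratio of 4.85 (1.30 to 21.99). Eomes, a trophoblast regulator, had a ratio of 2.77 (0.877 to 8.97), an interval that includes 1. The listed peak in Nanog, a core pluripotency factor, had 7 tags but 1 unique read against 3 in the control, a ratio of 0.808 (0.0154 to 10.1), so no excess was detectable there at this depth. Sox2 and Cdx1 had no listed peak within 20 kb of a start.

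Whether the listed centres marked CDX sites was asked through sequence. The CDX motif lay within 100 bp of 49.3% (48.9 to 49.8) of the centres and in 21.1% of the flanks, a ratio of 2.34 (2.31 to 2.37). This ratio was 2.81 for peaks with a GC content under 36% and 1.57 for those with 44% or more. The same letters in reversed order were found in 23.3% and 20.6%, with ratios of 1.48 and 0.631 in the same GC classes. At the peak upstream of Klf5 the site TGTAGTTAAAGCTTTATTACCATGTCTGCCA at positions 99680294 to 99680324 of chromosome 14 had its motif 2 bp from the centre, and the Klf5 window held 4 matches. The Krt20 peak had its motif, in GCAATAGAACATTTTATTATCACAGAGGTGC at positions 99298242 to 99298272 of chromosome 11, also 2 bp from the centre. The Hoxa7 peak had a motif 65 bp from the centre, in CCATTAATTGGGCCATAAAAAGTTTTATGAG at positions 52166802 to 52166832. The Myod1 peak held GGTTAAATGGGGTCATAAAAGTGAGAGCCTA at positions 53617214 to 53617244 of chromosome 7. Of the 34 best peaks of the named list genes, 27 had a CDX motif within 100 bp; those of Krt18, Msx2, Fabp1, Nkx1-2, Rbfox3, Gapdh and Tbp did not. Peaks with 2 or more matches made up 15.7% of those with 6 or 7 tags and 52.3% of those with 30 to 59 tags. The pooled ratio to control was 5.03 (4.99 to 5.07) without a match, 7.71 with 1, 11.1 with 2 and 14.5 (14.2 to 14.9) with 3 or more. These ratios were not adjusted for GC content and include the peaks at copies of the repeated sequence. The motif lay in 70.2% of peaks with a GC content under 36% and 51.8% of those with 36 to 40%. Outside peaks the ratio to control also ran from 0.223 at a GC content of 58% or more to 1.90 under 34%. Among 6-base words at peaks with at least 15 tags, CATAAA had the highest score, in 52.1% of the centres and 16.4% of the flanks. In reads, the motif was in 13.9% of Cdx2-FLAG reads in peaks and 5.01% of control reads there, against 4.86% and 2.03% outside.

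**Figure D4:**
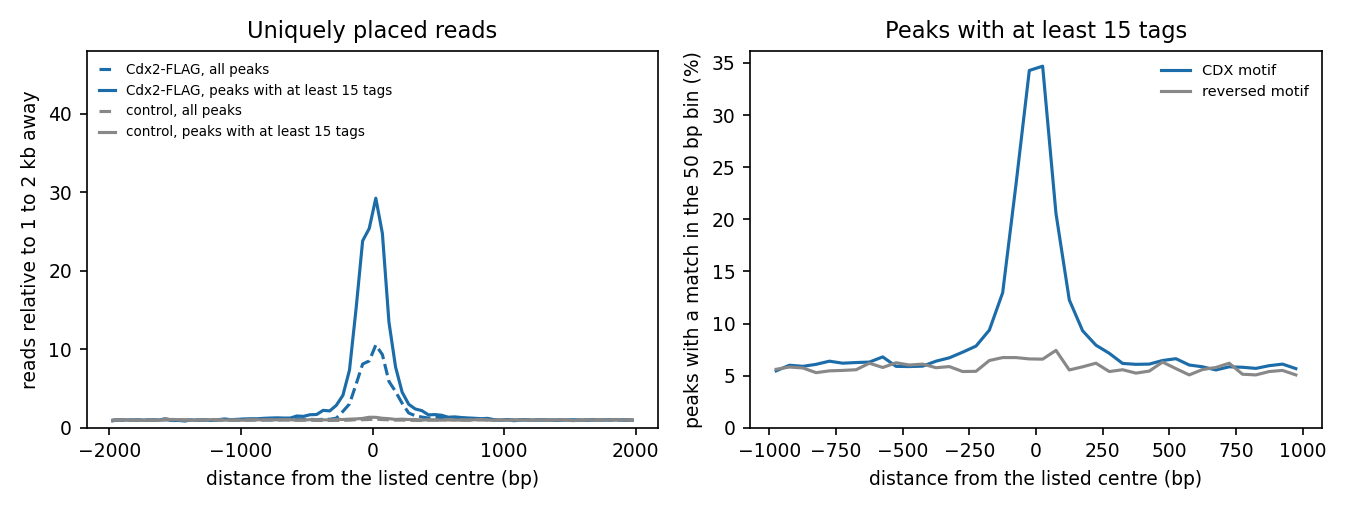
Left, uniquely placed reads in 50 bp bins around the listed centres, relative to bins 1 to 2 kb away, for both libraries. Right, percent of peaks with at least 15 tags that had a CDX motif or the reversed motif in each 50 bp bin. The Cdx2-FLAG reads reached 29.2 at the centres of peaks with at least 15 tags and 10.5 at all peaks, against 1.34 and 1.11 for the control.

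Over all peaks, motifs of other factors were less enriched. The POU octamer was in 1.48% of the centres and 1.60% of the flanks, the SOX motif in 29.2% and 28.9%, the GATA motif in 42.3% and 37.7%, the AP-1 motif in 3.08% and 3.36%, the TCF and LEF motif in 17.8% and 18.3%, and the KLF and SP motif in 0.404% and 0.742%. The HOX-PBX motif was in 4.28% and 2.25%, and in 7.45% and 2.37% among peaks with at least 15 tags. Among peaks with 30 to 59 tags the ratio of centres to flanks was 8.24 for HOX-PBX (12.8% and 1.56%) and 5.38 for TEAD, against 3.35 for CDX. The TEAD motif was in 3.93% of the centres and 2.86% of the flanks, and in 8.86% and 3.06% among peaks with at least 15 tags. Without the peaks at copies of the repeated sequence the last pair was 3.66% and 3.02%, HOX-PBX was in 5.16% and 2.44%, and CDX was still in 66.5% of the centres against 19.8% of the flanks.

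Listed peaks were seldom at promoters. Within 1 kb of a start lay 2.16% (2.05 to 2.28) of the peaks, 3.06% of random positions and 6.46% of control reads. The peak in the first kilobase of Hoxa7 was of this class, while those of Dlgap1, Slc25a17, Tfap2a and Krt20 were of the intronic class, with 37.96% of all peaks against 34.5% of random positions. Sites between genes, like those of Klf5 and Zfp42, made up 58.3% against 60.2%. Random positions were not matched on GC content. Listed peaks per Mb ran from 43.2 at a GC content under 34% to 4.97 at 58% or more. Outside peaks, Cdx2-FLAG reads per window ran from 1.02 to 0.428 between the same classes. A low share near starts can therefore not be ascribed to binding alone. Chromosome X held 5.29 peaks per Mb and the autosomes 20.5 to 26.8. Reads per base on chromosome X relative to the autosomes were 0.479 for Cdx2-FLAG and 0.355 for the control.

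The shape of the sites was measured from the strands of the reads. In the listed peaks, plus and minus strand read starts paired most often at a lag of 30 bp, near the 32 matched bases of a read. There Cdx2-FLAG had 8.35 and the control 1.48 times as many pairs as at lags of 350 to 400 bp. From 50 bp upwards, the smoothed number was highest at 165 bp for Cdx2-FLAG, 4.17 times, and at 50 bp for the control, 1.15 times. Without use of the list, 6480 windows of 500 bp were called, and 6371 (98.3%) overlapped a listed peak. The list rests on the same library, so this overlap was built in and is no independent test. The windows covered 6143 peaks (10.4% of the list). Between the control lanes, 2843 windows were called for lane 7 against lane 8 and 15 the other way, of which 24 and 1 overlapped a listed peak.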

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

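For the reads without a place, the tests were written before their results were seen. Of the Cdx2-FLAG reads, 55.9% had no place in mm9, against 22.1% of the control reads, and 19.2% and 24.3% in control lanes 7 and 8. This stood out because such reads enter none of the comparisons and were more frequent than in the control. Adapters or a few other technical sequences with their first 20 bases intact are argued against. The 100 most frequent 20-base starts made up 0.112% of these reads (control 2.11%). Of the reads that matched mm9 nowhere, 1.53% shared their first 20 bases with another (control 4.05%). This lay below the mark set against an organism with a small genome, but it cannot settle that question. Both reads had to be free of errors in these bases. Of the placed Cdx2-FLAG reads, 71.1% held bases 1 to 20 exactly in mm9 (control 88.4%). Sequencing errors in mouse reads stay open. A 20-base stretch found exactly in mm9 was in 11.5 percentage points more of these reads than of shuffled ones (control 11.6). This lay between the 10% and 30% set as bounds. It cannot show how much errors account for, since mouse reads with more than 2 mismatches often keep no such stretch intact. Of the placed Cdx2-FLAG reads, 52.2% had 0 mismatches against 79.98% in the control. No biological explanation was tested.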

How the results depend on the processing

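Alternatives with windows of 200 or 1000 bp, single control lanes, at least 15 tags, GC content, neighbouring genes or copies left out were chosen after the data were seen. Of the alternative values for results that answer a comparison, 32 stayed within the limits set for them, 24 moved, 4 lost the threshold and 2 reversed; where no cause is named, the cause was not tested. Hox genes with a peak stayed past the threshold except in 2 alternatives: at 100 kb, where 39 of 39 members met a random median of 37, near the ceiling, and against runs of neighbouring genes, where 33 met a median of 22 (adjusted permutation p = 0.0750). For olfactory receptors 430 with at least the median tags (random median 403, adjusted permutation p = 0.0650) and 168 after GC division (168) lost the threshold. Their order reversed for 69 with at least 15 tags (75) and for 701 against GC-matched lists (711). Lists past the threshold were 2, and 1 with at least the median tags, at 100 kb, with at least 15 tags and after GC division. The ratio of read shares in peaks, 6.83, was 6.49 with collapsed reads, 6.99 with exact matches, 6.56 with reads of up to 10 places, 7.36 scaled outside peaks, 9.85 and 4.28 in 200 and 1000 bp, and 7.77 and 6.18 with lane 7 and lane 8 alone. Enriched peaks, 16628, were 7432 and 7588 with lane 7 and lane 8 alone, where fewer control reads widen the intervals, and 2968 with a bound above 5. Other alternatives ran from 11550 to 17851. After GC division 13035 peaks were above 2, of which 11008 were among the 16628, and the share of peaks above 2 before it ran from 45.8% at a GC content under 34% to 8.57% at 58% or more. Peaks with at least the median tags were 32035. Reads without a place were 59.02% among distinct sequences. Peaks within 1 kb of a start were 1.47% with a bound above 2 and 1.34% with at least 15 tags. The motif ratio, 2.34, was 1.29 for the core, 2.87 in reads, 2.63 with at least the median tags and 3.13 after GC division. The 2.87 is for Cdx2-FLAG reads in peaks over those outside. Control reads also held the motif more often in peaks, 5.01% against 2.03%, so a raised value in reads was not particular to the Cdx2-FLAG library. Called windows in peaks were 1280 with at least 20 reads. Fixed windows of 500 bp were planned as an alternative and became the main measure. The 20 named peaks kept a bound above 2 in all 8 read settings, but their median bound, 43.5, was 21.2 and 24.2 with lane 7 and lane 8 alone, 29.3 with collapsed reads, and 29.02 and 28.1 in 200 and 1000 bp. These peaks were chosen for the highest bounds from the same reads, so staying above 2 was built in. With list genes included, 37 of the 54 named peaks were above 2 with lane 7 alone against 51 with both lanes. No paired analysis was possible because each group had 1 library, which also rules out leaving 1 out. Depth limits single peaks, with medians of 6 Cdx2-FLAG and 2 control reads.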

Other observations

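For the repeated sequence, the sequence itself and all its counts were found after the data were seen, as was the test of extra copies; for the olfactory receptors, the test by division at the same GC content was chosen after its result was seen. The sites with the highest bounds shared a sequence, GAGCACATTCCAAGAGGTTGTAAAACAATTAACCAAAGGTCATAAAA, among others at introns of Dlgap1, Slc25a17, Trim24, Csmd3, Kcnu1, Acnat1 and Lgi1 and at sites between genes near Scarb2 and Lnpep. In mm9 it had 1009 copies with at most 12 mismatches. Of these copies 737 (73.0%) had a listed peak within 150 bp, against 8 (0.793%) for positions 50 kb from each peak. Copies with 0 to 3 mismatches had a peak in 89.3% (85.8 to 92.0) of cases, and a pooled ratio to control of 61.8 (55.9 to 68.4). Peaks at copies were 1.25% of the list, 9.22% (8.42 to 10.1) of the peaks with at least 15 tags and 24.95% of those with 30 to 59 tags, but 12.8% (5.98 to 25.2) of the 47 with 60 or more. Their pooled ratio was 51.1 (47.7 to 54.8), and that of the other peaks was 6.58 (6.54 to 6.62). The sequence has a CDX motif near its end and holds a TEAD motif near its start. With the peaks at copies left out, the Hox list still had 33 of 39 members with a peak, against a length-matched median of 19. It had 27 with a peak above 2 after division at the same GC content, against a random median of 6. These counts were not set against runs of neighbouring genes. With all peaks, the 33 did not pass against such runs (adjusted permutation p = 0.0750).

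Reads from other copies would bring mismatches. Reads with 0 mismatches were 60.5% at copies and 51.8% in other peaks with at least 15 tags, a difference of 8.62 points. That cannot settle it, since reads with mismatches in repeated sequence more easily lose their unique place, which alone can raise the exact share. Extra copies in the cells would add reads to both libraries alike. The ratio of Cdx2-FLAG to control reads over all 1009 copies, with or without a peak, was 42.1 (39.5 to 44.8). As the sequence came from the peaks with the highest bounds and 737 copies had a peak, a high ratio was built in. It is thus no independent test. Uniquely placed control reads at the centres, 0.607 (0.528 to 0.696) of those 1 to 2 kb away, decide nothing, since reads in repeated sequence lose their unique place. Copies with a CDX motif at its place had a peak more often than copies without one, by 26.7 points (21.4 to 31.9). This was weighted over classes of other mismatches, from 0 to 2 up to 9 to 12. In the last class the shares were 72.3% and 65.2%. Binding through that motif would give such a difference. As the sequence was found in these peaks, binding of Cdx2-FLAG to a family of repeated sites is a hypothesis. Of copies without the motif at that place and with 0 to 2 other mismatches, 72.7% also had a peak. Motifs elsewhere in or beside them were not counted there, and 648 of all 737 peaks at copies had a CDX motif within 100 bp. Whether the hypothesis leaves those copies unexplained is therefore open.

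Olfactory receptor genes, which encode odorant receptors of sensory neurons, had a peak more often than length-matched genes. The GC content of their regions may account for this: against lists matched on it, 701 genes stood at percentile 24.7, although genes near a peak with a bound above 2 were fewer than in such lists, 287 against 328 (302 to 353). A background of either library that follows GC content is also open, since outside peaks the ratio of Cdx2-FLAG to control reads ran from 1.90 at a GC content under 34% to 0.223 at 58% or more, and after division by it 168 genes lay near a peak above 2 against a random median of 168. Between these classes reads per window ran from 0.381 to 3.39 in control lane 7, from 0.918 to 1.26 in lane 8 and from 1.02 to 0.428 for Cdx2-FLAG, so the lanes differed and lane 7 moved most. The CDX motif was in 54.4% of peaks near these genes and 25.3% of their flanks, an excess of 29.1 points (24.9 to 33.3). Over all listed peaks the excess was 28.3 points, and in other peaks of the same GC content 34.5. The interval lay below this last value, which had been set as the mark against CDX sites bound as in other peaks. As 34.5 has no interval and tags were not matched, the difference does not decide the question. None of the comparisons of these genes with random lists allowed for peaks shared by neighbours.

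For chromosome X, the tests were written before their results were seen, and their values are given with no weighing. Called windows per Mb were 0.684 on chromosome X and 1.90 to 3.04 on the autosomes. With the autosomal reads of both libraries thinned to the density of chromosome X they were 0.588 on chromosome X and 0.386 to 0.653 on the autosomes, a range that includes it. CDX motifs per Mb were 1359 on chromosome X, above the 987 to 1267 of the autosomes.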
